A study of Homo sapiens with 9 samples.

How the data were processed

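RNA sequencing data from 9 libraries of SW480 cells and their derivatives were analysed, with 3 libraries in each of 3 groups: the parental line (SW480), a clone with the empty pEF vector (CONTROL) and a clone with pEF carrying myc-tagged APC (APC). Per the labels, polyadenylated RNA was prepared with a TruSeq kit 72 h after plating, both clones but not the parental line were kept in G418, and fewer cells were plated for APC than for the other lines, in a ratio of 2 to 3.35. The replicates were parallel plates of 1 line per group, so p-values measure only the spread between plates.

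The deposited counts were whole numbers of reads per RefSeq transcript that had not been normalised, per the file headers and the values. The deposited RPKM values were made by the authors from those counts: RPKM equalled the count divided by the deposited transcript length and 1 constant per library for 100% of transcripts, within a relative tolerance of 0.0001. Per the submitters' processing notes, the tools were Trimmomatic, TopHat and GATK, without versions, and the genome build was hg19. The counting tool and the annotation release are not given in the sources used here. The count table held 39276 transcripts of 20876 genes, and 4738 further transcripts of the RPKM table were absent from it, each with an RPKM of 0. In 5096 genes the transcript with the next highest count had a median of 98.4% of the highest, so a read was counted for each transcript it overlapped. For this reason 1 transcript per gene was used, the one with the highest total count. Of 65 transcripts with gene names altered to dates, 62 were repaired through their accession. Gene names and gene order came from a RefSeq table of assembly GRCh38.p14, which matched 20193 of the 20876 transcripts. Its build differs from that of the counts, so no coordinates are given.

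Total counts over genes were 18272221, 18092102 and 18491724 in SW480 replicates 1 to 3, 18648765, 16454637 and 19355496 in CONTROL, and 18463511, 17608835 and 17211154 in APC. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 1.37 to 5.66. Library preparation also adds spread, so this alone does not show that they are separate samples. Each plate was counted as its own sample. Every column was assigned to a sample by its name.

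Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit, glmQLFTest) in 1 fit of all 9 libraries, which left 14253 genes. The biological coefficient of variation was 3.6%. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Gene lists with at least 5 measured members, 28 of 29, were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over 84 tests, and again with an estimated correlation and with fry. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1.

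Named genes were 9 fixed genes, the 10 APC-responsive genes per direction with the largest smaller fold change of the APC comparisons (mean CPM of at least 10 in the higher group or groups, APC libraries beyond all others), the 6 per direction with the largest change between CONTROL and SW480 (mean CPM of at least 10 in the higher group, no overlap of libraries), and from each list up to 3 responsive members per direction and 2 from CONTROL against SW480 by adjusted p. Examples in the text come from these, and some of the genes the rule names are not reported here. Genes with 3 or fewer counts in the lower group are given as a ratio with an exact 95% counting interval, or against a floor of 3 counts per library where the group had 0 counts.

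The tests were tested on simulated data, with 200 of 14253 genes changed. At 2-fold edgeR recovered 87% of the changed genes for APC against SW480, 93% for APC against CONTROL and 95% for CONTROL against SW480, and at 1.5-fold 77%, 85% and 79%. It called 17, 23 and 11 unchanged genes and no changed gene in the wrong direction. A list of 44 genes shifted 1.5-fold was recovered in each comparison with 0 other lists. The simulated genes were drawn independently of each other, whereas estimated correlations within the real lists reached 0.576. The simulation therefore does not show how the list test behaves with correlated genes. Its 200 changed genes were also far fewer than the 72.5%, 70.2% and 50% of genes called in the real comparisons. It thus does not show how the scaling and the gene test behave when so many genes differ.

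Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, counts summed over transcripts, limma on log2 RPKM with a pseudocount of 1 or 0.1, fits of 6 libraries, a replicate block, a minimum fold of 2 and leaving out each library. Leaving out the ribosomal RNA precursor was added after the data were seen. Transgene and endogenous APC reads were not separated, and sequence variants were not analysed here.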

Results

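Messenger RNA was measured by polyadenylated RNA sequencing in SW480, a human colorectal cancer cell line that lacks functional APC, and in 2 lines derived from it. The line referred to as CONTROL carried the empty pEF vector, and the line referred to as APC carried pEF with myc-tagged APC, a scaffold of the complex that marks beta-catenin for destruction. Each of the 3 groups held 3 libraries, from plates harvested 72 h after plating. Total counts over genes, taking 1 transcript per gene, ranged from 16454637 in CONTROL replicate 2 to 19355496 in CONTROL replicate 3, and 3 counts corresponded to 0.156 to 0.184 CPM, the library-size normalised count used here. Per-gene levels are given as mean CPM ± SD with n = 3, and log2 fold changes with their standard error (SE). Replicates of a group correlated at 0.9972 or higher across genes (log2 CPM, Pearson), SW480 with CONTROL libraries at 0.9854 to 0.9873, and APC libraries with the others at 0.9283 to 0.9353. Genes are not independent replicates, so these coefficients only describe the libraries. The first principal component held 82.2% of the variance and separated the APC libraries from the other 6, and the second held 11.6%.

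APC transcript, the product of the introduced construct, was measured at 145 ± 5 CPM in the APC line, 47.9 ± 1.59 CPM in CONTROL and 49.3 ± 2.46 CPM in SW480. It was 2.94-fold higher in the APC line than in SW480 (log2 fold change 1.56 ± 0.05, edgeR adjusted p = 4.4e-25) and 3.02-fold higher than in CONTROL (1.60 ± 0.05, edgeR adjusted p = 2.6e-25). The difference between CONTROL and SW480 did not pass the test (−0.04 ± 0.05, edgeR adjusted p = 0.56). The deposited counts do not separate the construct's transcript from that of the cells' own gene. CTNNB1, which encodes beta-catenin, stood at 1348 ± 52.5 CPM in SW480, 938 ± 20.4 CPM in CONTROL and 429 ± 4.71 CPM in the APC line. AXIN2, a feedback target of beta-catenin, stood at 748 ± 22.1, 571 ± 5.43 and 86.0 ± 3.36 CPM in the same order. MYC, a transcription factor gene often listed among the targets of the pathway, moved the other way, from 118 ± 2.38 CPM in SW480 to 147 ± 5.62 CPM in CONTROL and 283 ± 2.75 CPM in the APC line.

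**Figure D1:**
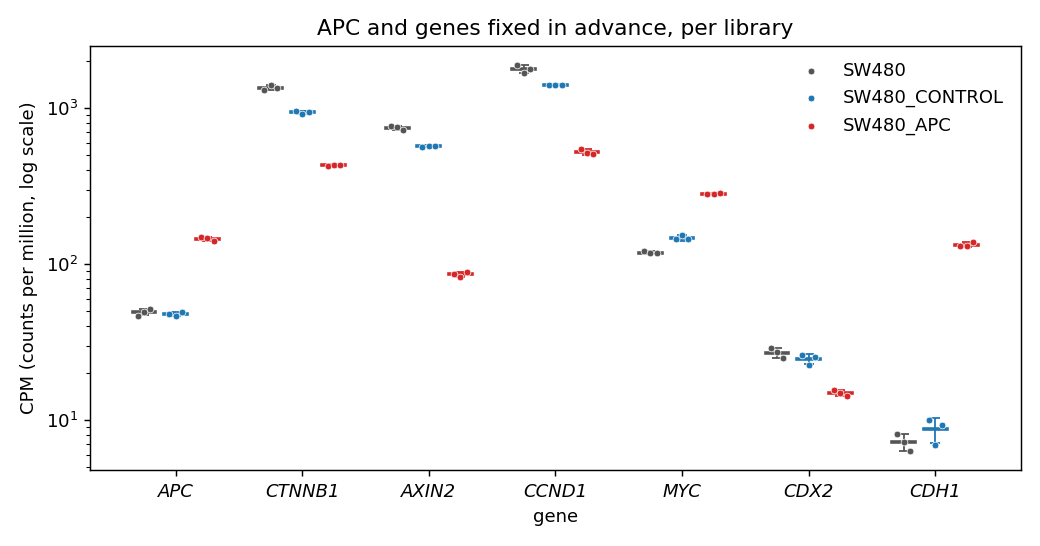
CPM on a log scale for 7 genes chosen before the data were examined, with 1 point per library, a bar at the group mean and whiskers of 1 SD (n = 3 per group). APC, MYC and CDH1 were higher in all 3 APC libraries than in the other 6, and CTNNB1, AXIN2, CCND1 and CDX2 lower.

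The first comparison, APC against SW480, addressed how expression differed between the line carrying the APC construct and its parent. AXIN2 was 8.71-fold lower in the APC line (log2 fold change −3.12 ± 0.04), and NKD1 and APCDD1, which encode feedback inhibitors of Wnt signalling, were 8.47-fold and 15.9-fold lower. CCND1, the cyclin D1 gene, fell 3.39-fold from 1774 ± 107 to 524 ± 21.6 CPM, and CTNNB1 fell 3.14-fold, while the 24 expressed genes nearest to it had a median log2 fold change of −0.44. CDH1, which encodes the epithelial adhesion protein E-cadherin, was 18.3-fold higher (4.2 ± 0.08), rising from 7.24 ± 0.897 to 133 ± 4.49 CPM. CDX2, an intestinal transcription factor gene, was 1.81-fold lower, at 14.9 ± 0.650 against 27.1 ± 2.02 CPM. In all, 10333 of 14253 genes tested differed between these lines (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 5078 higher and 5255 lower in the APC line. The fitted change was over 2-fold for 1127 of the higher and 1589 of the lower genes, and the median absolute log2 fold change of the called genes was 0.51. In 73.1% of the genes tested the 3 libraries of one line did not overlap those of the other, against 10% by chance.

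The second comparison, APC against CONTROL, used the vector line to take changes that come with transfection and selection into account. The same direction was measured for the fixed genes: AXIN2 was 6.64-fold lower (−2.73 ± 0.04), CCND1 2.68-fold lower (−1.42 ± 0.04), CTNNB1 2.19-fold lower (−1.13 ± 0.04), CDX2 1.66-fold lower (−0.73 ± 0.08), CDH1 15.1-fold higher (3.91 ± 0.07) and MYC 1.92-fold higher (0.94 ± 0.04). LGR5, an intestinal stem cell gene, was too low to be tested, with 8, 3 and 7 counts in the APC libraries, 0 in CONTROL and 1 in SW480. Its ratio to SW480 was 19.1 (95% counting interval 3.02 to 796), and it was at least 2.04-fold higher than in CONTROL. KRT20, a marker of differentiated colon epithelium, had at most 5 counts in any library. Of the 14253 genes, 10004 differed between APC and CONTROL, 4958 higher and 5046 lower in the APC line, with 1230 and 1381 of them over 2-fold. The groups did not overlap for 73.4% of the genes tested, against 10% by chance.

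Genes called in the same direction in both of these comparisons are referred to as APC-responsive. There were 7951, of which 3968 were higher and 3983 lower in the APC line, and 2097 changed over 2-fold in both comparisons (930 higher, 1167 lower). The comparisons share the APC libraries. Simulated groups without any effect gave a mean of 0.15 genes called in the same direction in both (20 simulations, at most 1), and independent lists of the observed sizes would share 1766 higher and 1860 lower genes. The fold changes of the comparisons correlated at 0.912 across genes (0.509 in the simulation), with a covariance of 1.4979 (0.0104 in the simulation, a difference of 1.4874). The 3 shared libraries were not split between the comparisons, since 1 part would hold a single library, so part of the excess may come from them. Another 379 genes were called in both comparisons in opposite directions. Of the APC-responsive genes, 4126 were not called between CONTROL and SW480, while 2070 were called there in the direction of the APC line and 1755 in the opposite direction.

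The APC-responsive genes with the largest increases were chosen by a rule that took 10 per direction. C3, a complement component gene, rose from 1.15 ± 0.0622 CPM in SW480 and 1.36 ± 0.415 CPM in CONTROL to 425 ± 15.3 CPM, 368-fold and 309-fold. CCL2, a monocyte-attracting chemokine gene, rose from 0.197 ± 0.0816 and 0.0736 ± 0.0297 CPM to 94.0 ± 4.84 CPM. FOXJ1, a regulator of motile cilia, reached 31.4 ± 2.82 CPM, 238-fold above SW480 and 317-fold above CONTROL. FXYD3, which encodes a regulator of the sodium pump, reached 26.6 ± 1.82 CPM, 339-fold and 195-fold above. Counting intervals and floors cover counting error only. GALNT3, a mucin-type glycosyltransferase gene, reached 28.1 ± 0.753 CPM, was at least 174-fold higher than in SW480 (0 counts, floor of 3 counts per library) and had a ratio of 759 to CONTROL (2 counts, 95% counting interval 210 to 6280). PLEKHS1, DNER, PXDN, IGFL1 and HLA-DRB1 completed the 10, at 10 to 15.8 CPM in the APC line and 0.0173 to 0.0716 CPM in the other groups. HLA-DRB1 shares reads with related HLA genes, so its value is uncertain.

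Among the lower genes, CXCL14, a chemokine gene, fell from 24.1 ± 2.19 CPM in SW480 and 26.6 ± 2.95 CPM in CONTROL to 1 count over the 3 APC libraries, ratios of 1270 to SW480 (95% counting interval 227 to 50200) and 1410 to CONTROL (252 to 55600). TNNC1, the slow and cardiac troponin C gene, fell from 69.3 ± 3.99 and 104 ± 2.09 CPM to 0.684 ± 0.0880 CPM. TMEM47, a junction-associated membrane protein gene, fell from 65.8 ± 2.90 and 21.1 ± 0.666 CPM to 0.324 ± 0.0427 CPM. MAOB, the monoamine oxidase B gene, was 46.3-fold and 33.2-fold lower, and KRT71, a hair follicle keratin gene, 46.4-fold and 47.3-fold lower. MAGEC2, a cancer-testis antigen gene, stood at 26.1 ± 0.847 CPM in SW480, 98.5 ± 3.19 CPM in CONTROL and 0.248 ± 0.136 CPM in the APC line. PDE2A, TENM2, SLIT1 and PSG1 were the other 4 of the 10, with log2 fold changes against SW480 of −6.90, −6.28, −5.18 and −5.70. PSG1 belongs to a family of closely similar genes that can share reads.

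Groups of genes fixed before the data were examined were then compared by the number of their members that were APC-responsive and by a test of the whole list against the other genes (camera). Of 28 lists tested, 9 passed the threshold in APC against SW480 and 9 in APC against CONTROL (camera on voom values, preset inter-gene correlation of 0.01, adjusted p under 0.05 over 84 tests), of which 8 were shared. With an estimated correlation 2 lists passed in each, the inflammatory and the antigen presentation lists. Most lists lost had estimates above the preset 0.01. The fibroblast list against SW480 was lost at an estimate of −0.066, so a higher correlation alone does not explain each loss. Counts of responsive members adjusted over the list alone were identical to those over all genes tested, except where another value is given. Of all 14253 genes tested 55.8% were APC-responsive, 3968 higher and 3983 lower. A list with members in both directions is therefore not unusual by itself.

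Wnt and beta-catenin targets fell as a list: 20 of 31 measured members were lower and 8 higher. The median log2 fold change was −1.16 against SW480 and −0.83 against CONTROL (camera adjusted p = 0.000184 and 0.00701; adjusted p = 0.211 and 0.294 with an estimated correlation). Members that rose included DKK4, which encodes an inhibitor of Wnt signalling, from 0.931 ± 0.0798 CPM in SW480 and 0.164 ± 0.0426 CPM in CONTROL to 73.6 ± 1.52 CPM. PLAUR, the urokinase receptor gene, rose from 33.1 ± 1.81 and 37.6 ± 1.13 CPM to 91.9 ± 1.60 CPM. The list of Wnt pathway components, with 18 members higher and 15 lower of 44, did not pass (camera adjusted p = 0.956 and 0.727). The ligand genes within it moved apart: WNT10A rose from 2.54 ± 0.394 to 32.0 ± 1.39 CPM relative to SW480, whereas WNT5A fell from 190 ± 7.94 (132 ± 2.79 in CONTROL) to 53.1 ± 2.37 CPM and WNT11 from 10.9 ± 1.37 to 1.06 ± 0.0828 CPM, each also changed in that direction against CONTROL.

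Epithelial junction and adhesion genes rose as a list, with 24 of 35 measured members higher and 7 lower. The median log2 fold change was 1.29 against SW480 and 1.33 against CONTROL (camera adjusted p = 9.02e-06 and 3.62e-06; adjusted p = 0.0929 in both with an estimated correlation). EPCAM, an epithelial adhesion molecule gene, rose from 49.4 ± 1.16 and 42.4 ± 1.57 CPM in SW480 and CONTROL to 382 ± 15.9 CPM. CLDN7, a tight junction gene, rose from 5.96 ± 0.797 and 7.21 ± 0.477 to 146 ± 8.34 CPM, and ESRP1, an epithelial splicing regulator gene, from 1.36 ± 0.352 and 3.32 ± 0.306 to 88.2 ± 2.70 CPM. PVRL1, TJP1 and CTNNA1, which encode nectin-1, ZO-1 and alpha-catenin, were lower, with log2 fold changes against SW480 of −1.45, −0.43 and −0.28. Integrins, laminins and collagens also rose as a list, with 18 of 32 higher and 8 lower (camera adjusted p = 0.0239 and 0.00701; adjusted p = 0.350 and 0.294 with an estimated correlation). LAMA3 and LAMB1, which encode laminin chains, rose with log2 fold changes against SW480 of 2.05 and 1.27, while ITGA1 and ITGB5, integrin genes, fell by 1.35 and 0.71 on the log2 scale. Genes of the mesenchymal list went both ways, 10 of 22 higher and 9 lower (camera adjusted p = 0.965 and 0.727). ZEB1, a repressor of CDH1, fell from 43.6 ± 0.573 and 43.0 ± 2.78 CPM to 8.08 ± 1.21 CPM and FN1, the fibronectin gene, from 180 ± 10.6 and 166 ± 7.21 to 68.5 ± 1.71 CPM. The matrix-degrading proteases PLAU and MMP9 were higher instead, PLAU at 286 ± 7.15 against 8.97 ± 0.314 and 12.2 ± 0.205 CPM and MMP9 at 55.1 ± 0.869 against 0.430 ± 0.161 and 0.316 ± 0.0502 CPM.

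All 22 measured members of the NF-kappaB and inflammatory list were higher in the APC line. Their median log2 fold change was 4.52 against SW480 and 4.41 against CONTROL, or 4.39 and 3.94 with genes near 0 counts set at their bound (camera adjusted p = 2.2e-14 in both; adjusted p = 0.00463 in both with an estimated correlation). SAA1 and SAA2, acute phase genes with near-identical sequences that can share reads, reached 2232 ± 79.0 and 758 ± 32.6 CPM, against 108 ± 2.00 and 35.6 ± 1.94 CPM in SW480 and 380 ± 9.05 and 127 ± 1.28 CPM in CONTROL. All 12 measured members of the antigen presentation list were higher as well, with medians of 1.51 and 1.63 (camera adjusted p = 8.61e-08 and 5.81e-08; adjusted p = 0.0171 in both with an estimated correlation). CD74, the class II invariant chain gene, rose from 7.13 ± 0.968 and 8.21 ± 0.869 CPM to 282 ± 20.1 CPM and B2M, the class I light chain gene, from 306 ± 15.4 and 354 ± 2.41 to 806 ± 32.0 CPM. Of the interferon response list 14 of 26 members were higher and 6 lower, and it did not pass (camera adjusted p = 0.07 and 0.117), although against SW480 it passed without APC replicate 1 or without CONTROL replicate 1. IRF1 rose from 39.1 ± 0.909 and 38.3 ± 1.57 to 127 ± 1.11 CPM and IFITM2 fell from 349 ± 9.97 and 402 ± 2.45 to 106 ± 2.79 CPM.

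Markers of other cell types were read in the same libraries. PTPRC, COL3A1 and DCN, abundant in leukocytes and fibroblasts, had no entry among the counts and were listed at an RPKM of 0 in every library, and PECAM1, an endothelial gene, stood at 0.209 CPM in the APC line. Of the leukocyte list 3 of 6 measured members were higher and 1 lower (camera adjusted p = 0.669 and 0.149). The lower member was HBA1, a haemoglobin gene. The higher members were CORO1A, ITGAM and CD68, with CORO1A at 30.6 ± 0.760 CPM against 13.8 ± 0.839 and 7.94 ± 1.04 CPM. ITGAM had ratios of 19.1 to SW480 (3 counts, counting interval 6.2 to 95.6) and 27.8 to CONTROL (2 counts, 7.33 to 235). Of the fibroblast list 4 of 5 were lower, among them FBLN1 and PDGFRB, and the list passed against SW480 (camera adjusted p = 0.0462; adjusted p = 0.249 with an estimated correlation) but not against CONTROL (camera adjusted p = 0.0926). The first call was lost without APC replicate 2 or without CONTROL replicate 2, either of which left 8 lists past the threshold. The endothelial and neural list had 3 measured members and was not tested, and 1 of them, TUBB3, a neuronal tubulin gene, was lower, at 26.7 ± 2.76 CPM against 117 ± 7.28 and 74.7 ± 3.92 CPM.

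Replication-dependent histone transcripts, which normally end without a poly(A) tail, were lower in the APC line for 20 of 23 measured genes, with medians of −2.68 against SW480 and −2.42 against CONTROL (camera adjusted p = 1e-06 and 2.04e-05; adjusted p = 0.072 and 0.0929 with an estimated correlation). HIST1H2BK fell from 320 ± 13.2 and 309 ± 4.77 CPM to 31.1 ± 1.50 CPM and HIST2H2BE from 35.9 ± 0.709 and 35.4 ± 0.967 to 4.39 ± 0.568 CPM. Histone genes are closely similar, so reads can be split between them. Another untailed RNA, the 45S ribosomal RNA precursor, took 2.70% to 3.12% of gene counts in the APC libraries, 2.38% to 2.40% in CONTROL and 2.69% to 3.50% in SW480. S phase and mitosis genes went both ways, with 15 of 40 higher and 11 lower (16 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.761 and 0.727). BIRC5 and CCNA2, mitotic genes, were 0.62 and 0.41 higher than in SW480 on the log2 scale, and CCNE2, the cyclin E2 gene, fell by 0.76. Of the cell cycle inhibitors and p53 targets 3 of 23 were higher and 9 lower (camera adjusted p = 0.141 and 0.892). CDKN1A and CDKN1C, which encode p21 and p57, were 55.1 ± 3.11 and 1.85 ± 0.598 CPM in the APC line, against 94.0 ± 2.55 and 17.8 ± 3.26 CPM in SW480 and 77.8 ± 4.50 and 9.79 ± 0.760 CPM in CONTROL.

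**Figure D2:**
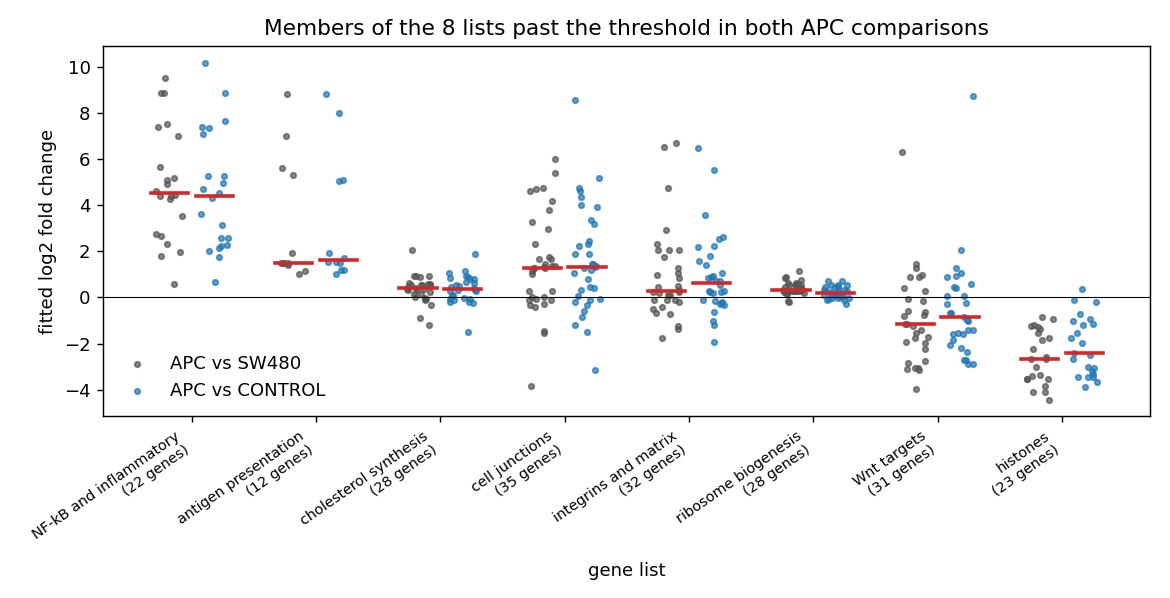
Fitted log2 fold changes of the measured members of the 8 gene lists that passed the camera threshold both in APC against SW480 (grey) and in APC against CONTROL (blue), 1 point per gene, with the list median as a red line. The inflammatory and antigen presentation members all lie above 0, with medians of 4.52 and 1.51 against SW480, and the histone median lies at −2.68. Fitted values of genes near 0 counts depend on the prior count.

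Cholesterol synthesis genes were higher for 17 of 28 members and lower for 2, with a median of 0.39 against SW480 and 0.38 against CONTROL (camera adjusted p = 0.00333 and 0.00551; adjusted p = 0.565 and 0.581 with an estimated correlation). FASN, the fatty acid synthase gene, rose from 251 ± 13.1 CPM in SW480 and 206 ± 4.09 CPM in CONTROL to 360 ± 22.9 CPM. Ribosome biogenesis genes were higher for 17 of 28 members and lower for 1, with medians of 0.31 and 0.19 (camera adjusted p = 2.24e-06 and 0.00816; adjusted p = 0.457 and 0.643 with an estimated correlation). NOLC1, a nucleolar phosphoprotein gene, rose from 281 ± 12.4 and 378 ± 2.24 to 624 ± 17.6 CPM. The unfolded protein and integrated stress response list, with 8 of 31 higher and 16 lower, passed only against CONTROL (camera adjusted p = 0.0102; adjusted p = 0.114 with an estimated correlation; 0.711 against SW480), where its median was −0.23. PHGDH, a serine synthesis gene, and VLDLR, a lipoprotein receptor gene, were lower, VLDLR at 5.87 ± 1.01 CPM against 41.4 ± 2.30 and 51.5 ± 2.35 CPM, while DDIT4, an inhibitor of mTORC1, was higher at 83.8 ± 5.16 against 9.22 ± 2.01 and 16.0 ± 1.61 CPM.

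Lists of intestinal cell fate did not pass the camera threshold in the APC comparisons. Absorptive cell genes were higher for 5 of 16 members and lower for 5 (camera adjusted p = 0.832 and 0.322), with KLF4 at 28.8 ± 0.737 CPM against 4.67 ± 0.662 in SW480 and EPS8L3 at 0.991 ± 0.0965 against 28.2 ± 1.11. Secretory cell genes were higher for 4 of 11 and lower for 3 (camera adjusted p = 0.727 and 0.485). MUC2, the goblet cell mucin gene, stood at 5.82 ± 1.02 CPM against 0.161 ± 0.142 in SW480, and DCLK1, a tuft cell gene, at 8.59 ± 0.834 against 121 ± 6.16 CPM. Stem cell genes were higher for 7 of 13 and lower for 3 (camera adjusted p = 0.69 and 0.285), LRIG1 at 97.9 ± 2.55 against 42.4 ± 1.33 CPM and TNFRSF19 at 4.44 ± 0.533 against 39.1 ± 3.39 CPM.

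Signalling lists also held members that moved in both directions. Of the EGF receptor and MAPK list 17 of 26 members were higher and 8 lower (camera adjusted p = 0.122 and 0.0568). The list passed against CONTROL in 7 of the 9 fits that left out 1 library, all but those without APC replicate 2 or CONTROL replicate 3. MET, the hepatocyte growth factor receptor gene, rose from 9.04 ± 0.688 to 109 ± 6.21 CPM relative to SW480, and DUSP6, an ERK phosphatase gene, fell from 717 ± 18.8 in SW480 and 521 ± 23.8 in CONTROL to 136 ± 6.10 CPM. TGF-beta and BMP genes were higher for 10 of 29 and lower for 14 (camera adjusted p = 0.285 and 0.671), ID2, an inhibitor of helix-loop-helix factors, falling from 338 ± 10.2 and 364 ± 13.0 to 15.7 ± 1.28 CPM and INHBB, an activin subunit gene, rising from 15.4 ± 0.585 and 8.71 ± 0.137 to 77.6 ± 2.51 CPM. Notch genes were higher for 5 of 20 and lower for 9 (camera adjusted p = 0.398 and 0.471), HES1 being at 18.1 ± 0.565 against 31.5 ± 0.973 CPM in SW480. YAP and TAZ targets were higher for 10 of 23 and lower for 8 (camera adjusted p = 0.471 and 0.702). CTGF fell from 28.5 ± 1.46 in SW480 and 18.4 ± 0.804 in CONTROL to 2.14 ± 0.478 CPM, and F3, the tissue factor gene, rose from 8.34 ± 0.573 to 100 ± 3.77 CPM. Retinoid genes were higher for 6 of 16 and lower for 6 (camera adjusted p = 0.892 and 0.956). ALDH1A3, which makes retinoic acid, rose from 148 ± 3.15 and 113 ± 4.01 to 1022 ± 6.04 CPM, and TGM2, a transglutaminase gene, fell from 3817 ± 157 and 2667 ± 45.4 to 1337 ± 35.1 CPM.

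Stress and metabolic lists completed the set. Hypoxia and glycolysis genes were higher for 12 of 31 members and lower for 7 (camera adjusted p = 0.0796 and 0.398). SLC2A3, a glucose transporter gene, fell from 1252 ± 28.2 in SW480 and 843 ± 18.5 in CONTROL to 264 ± 5.55 CPM, and ANGPTL4 rose from 4.21 ± 1.05 and 2.20 ± 0.332 to 44.3 ± 2.21 CPM. Heat shock and immediate early genes were higher for 2 of 21 and lower for 10 (camera adjusted p = 0.082 and 0.0869; past the threshold against SW480 without APC replicate 1), and the immediate early genes FOS and EGR3 fell by 3.70 and 3.68 on the log2 scale. NRF2 targets and detoxification genes were higher for 9 of 27 and lower for 10 (camera adjusted p = 0.727 and 0.697), with MGST1 at 64.4 ± 1.68 against 1.61 ± 0.247 CPM in SW480 and 4.33 ± 0.5 CPM in CONTROL. Cancer-testis antigen genes were lower for 2 of 5, MAGEC2 and PRAME (camera adjusted p = 0.394 and 0.122). The median, the mean and the camera direction did not share a sign for 8 lists against SW480 and 5 against CONTROL, none of them past the threshold.

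The third comparison, CONTROL against SW480, measured changes of the vector line that do not involve the APC construct. AXIN2 was 1.31-fold lower in CONTROL (log2 fold change −0.39 ± 0.04), CCND1 1.26-fold lower and APCDD1 2.17-fold lower. CTNNB1 was 1.44-fold lower, and the 24 expressed genes nearest to it had a median log2 fold change of −0.37. MYC was 1.25-fold higher, CDX2 did not pass the test (−0.13 ± 0.07, edgeR adjusted p = 0.11), and CDH1 was 0.28 ± 0.11 higher on the log2 scale, a call with an edgeR adjusted p of 0.042 that was lost under 8 of 16 alternatives (adjusted p 0.0023 to 0.256 over them). In all, 7130 of the 14253 genes tested differed, 3610 higher and 3520 lower in CONTROL, with 239 and 460 of them over 2-fold. The median absolute log2 fold change of the called genes was 0.32, and the groups did not overlap for 56.6% of the genes tested, against 10% by chance. Among the largest increases of genes with a mean of at least 10 CPM in the higher line, G0S2, an inhibitor of lipolysis, rose from 1.99 ± 0.542 to 24.4 ± 0.797 CPM, RYR2, a calcium channel gene, from 1.27 ± 0.435 to 13.9 ± 0.989 CPM and CDK15 from 9.54 ± 0.788 to 84.2 ± 3.40 CPM. UST, PAPPA and IFI27 followed, with log2 fold changes of 3.06, 3.01 and 2.08. Among the largest decreases under the same minimum, ROBO1, an axon guidance receptor gene, fell from 12.6 ± 0.256 to 0.189 ± 0.119 CPM, GNAI1, a G protein subunit gene, from 28.0 ± 3.04 to 2.07 ± 0.222 CPM and VAT1L from 33.0 ± 0.916 to 3.21 ± 0.471 CPM. UNC13A, EDN3 and CDH11 fell by 3.63, 3.14 and 3.08 on the log2 scale.

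Of the 28 lists, 9 passed in CONTROL against SW480, 5 higher and 4 lower, and with an estimated correlation 1 did. That list was the unfolded protein and integrated stress response, with 18 of 31 members higher and 2 lower (median 0.24, camera adjusted p = 1.77e-06; adjusted p = 0.0324 with an estimated correlation), SLC7A11, the cystine transporter gene, rising from 5.55 ± 0.486 to 23.1 ± 0.960 CPM. Ribosome biogenesis was higher for 20 of 28 and lower for 1 (20 and 2 adjusted over the list alone; camera adjusted p = 2.14e-05; adjusted p = 0.461 with an estimated correlation). NRF2 targets were higher for 16 of 27 and lower for 4 (16 and 6 adjusted over the list alone; camera adjusted p = 0.0053; adjusted p = 0.211 with an estimated correlation), TXNRD1, the thioredoxin reductase gene, rising from 326 ± 23.2 to 579 ± 28.8 CPM. Cancer-testis antigens, MAGEC1 and MAGEC2, were higher for 2 of 5 (4 adjusted over the list alone; camera adjusted p = 0.0374; adjusted p = 0.294 with an estimated correlation). The inflammatory list had 8 of 22 members higher and none lower (7 adjusted over the list alone; camera adjusted p = 0.0444; adjusted p = 0.211 with an estimated correlation), with SAA1 3.53-fold up. Lower lists were the Wnt targets, with 20 of 31 lower and 9 higher (21 and 9 adjusted over the list alone; median −0.34, camera adjusted p = 0.000751; adjusted p = 0.211 with an estimated correlation), and the histones, with 10 of 23 lower and 1 higher (camera adjusted p = 0.0204; adjusted p = 0.294 with an estimated correlation). Secretory genes were lower for 7 of 11 and higher for 1 (camera adjusted p = 0.0444; adjusted p = 0.232 with an estimated correlation), CHGA, the chromogranin A gene, falling from 4.94 ± 0.559 to 0.205 ± 0.0424 CPM. Cell cycle inhibitors were lower for 12 of 23 and higher for 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0432; adjusted p = 0.392 with an estimated correlation). The calls of the secretory, inhibitor and inflammatory lists were lost without CONTROL replicate 2, which left 6 lists, the secretory call also without CONTROL replicate 3 and the inhibitor call also without SW480 replicate 1.

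Lists that did not pass between CONTROL and SW480 had camera adjusted p values from 0.0869 for TGF-beta and BMP genes, 4 of 29 higher and 10 lower (4 and 9 adjusted over the list alone), to 0.99 for Notch genes, 4 of 20 in each direction. EGF receptor and MAPK genes were lower for 12 of 26 and higher for 6 (14 and 7 adjusted over the list alone), a list that passed without CONTROL replicate 1 or without SW480 replicate 1, and YAP and TAZ targets higher for 11 of 23 and lower for 4 (12 and 4 adjusted over the list alone). Junction genes were higher for 7 of 35 and lower for 12 (8 and 12 adjusted over the list alone) and antigen presentation genes higher for 1 of 12 and lower for 1. For 6 lists the median, mean and camera direction did not share a sign, none of them past the threshold. Relative to SW480, 1854 genes were higher and 2054 lower in both derived lines, against 1286 and 1298 for independent lists and a mean of 0.4 such genes in simulated groups without any effect. The fold changes of the derived lines against SW480 correlated at 0.225 across genes (0.49 in the simulation), with a covariance of 0.1554 (0.0099 in the simulation, a difference of 0.1455). These comparisons share the SW480 libraries, which were not split either, so part of the excess may come from them. Each construct was represented by 1 line, and the APC line was plated at fewer cells than the other lines, so the construct, the line and the density fall together in these libraries.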

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

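The tests of the inflammatory genes, the S phase genes and the stretches of neighbouring genes were chosen after the result was seen, while the test of RNAs without poly(A) tails and the regrouping of libraries were set beforehand.

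Genes that moved in opposite directions in the derived lines relative to SW480 numbered 1755, each also called different between the derived lines, and 145 of them changed over 2-fold in both lines. Among the named genes, the log2 fold change of APC against CONTROL was −8.6 for MAGEC2, −4.79 for IFI27 and −3.97 for UGT1A6, which were higher than SW480 in CONTROL and lower in the APC line. It was 8.73 for DKK4, 3.58 for TNC, 5.11 for ALCAM and 6.72 for CA9, which were lower than SW480 in CONTROL and higher in the APC line. What drew attention to all of these was the difference in response between the lines.

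Inflammatory and antigen presentation genes were higher in the APC line. Leukocytes, fibroblasts or endothelial cells in the cultures would bring their abundant transcripts, but the highest mean of 8 such markers in the APC group was 0.21 CPM, for PECAM1, against a median of 61.9 CPM for the inflammatory list. PECAM1 stood at 0 CPM in the other groups. Of the 6 measured members of the leukocyte list, CORO1A, ITGAM and CD68 were higher in the APC line. The 1 lower member was HBA1, a haemoglobin gene, so the result covers only the 8 markers. A scaling error between libraries would move all genes alike, yet both lists lay above other genes in both APC comparisons, with a camera adjusted p of at most 0.0171 at an estimated correlation. This is the list result that drew attention to these genes, not a separate test. A response of the cells to APC, to plating density or to the history of the clone may each underlie the pattern, and the design does not separate them.

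Histone transcripts were lower in the APC line, with median log2 fold changes of −2.68 (95% bootstrap interval −3.52 to −1.74) against SW480 and −2.42 (−3.07 to −1.17) against CONTROL. Less carry-over of RNA without poly(A) tails would lower other such RNAs, yet 17 of them had medians of 0.57 (−0.02 to 1.08) and 0.5 (0.25 to 1.27). All but the 45S ribosomal RNA precursor had group means of only 0.199 to 13.5 CPM, so many of these values rest on few counts. The precursor itself, at 29200 CPM in the APC line, had log2 fold changes of −0.02 against SW480 and 0.28 against CONTROL. Fewer cells in S phase would lower S phase genes, yet 17 of these had medians of −0.09 (−0.27 to 0.20) and −0.07 (−0.32 to 0.33). A change in how many histone transcripts carry poly(A) tails may underlie the pattern and was not tested.

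Neighbouring genes shifted together in both derived lines: medians over 25 expressed neighbours lay beyond 0.3 on the log2 scale for 1287 of 10352 genes in APC against SW480, 1632 in APC against CONTROL and 726 in CONTROL against SW480, while 100 shuffles of gene order reached at most 132, 94 and 0, so a shuffle reached the real number in 0 of 3 comparisons. In stretches found from every other gene, 83.5%, 85.5% and 90.7% of the left-out genes moved with their stretch. A copy number difference of chromosome segments would give this, although coordinated regulation of neighbours stays open. Neighbours that share exons or reads would also move together, and such genes were not removed. In APC against CONTROL the stretch from TAF7 to PCDH1 had a median of 1.39, as did the protocadherin gamma genes, which share exons. Between CONTROL and SW480 the 24 nearest expressed neighbours of CTNNB1 had a median of −0.37 (−0.49 to −0.30) beside −0.52 for CTNNB1, so its decrease there may be shared with its segment. Between APC and SW480 they had a median of −0.44 (−0.57 to −0.39), with 24 of 24 lower, beside −1.65 for CTNNB1, so part of that decrease may be shared as well. Between APC and CONTROL they had a median of −0.08 (−0.26 to 0.01), with 16 of 24 lower and the lowest at −1.14, beside −1.13 for CTNNB1, which argues against a shift of the whole segment as the cause of that decrease. The longer stretch around CTNNB1, from MTMR14 to TMEM42, held 118 genes with a median of −0.51 in CONTROL against SW480. The same genes had medians of −0.67 in APC against SW480 and −0.19 in APC against CONTROL. This stretch was found from the same fold changes.

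Other splits of the 6 libraries of each pair gave at most 0 called genes, against 10333, 10004 and 7130, and at most 7, 6 and 7 lists, against 9 in each. Only 1 of the 10 splits, the real one, reached the real value each time, but 10 splits are too few for a share under 0.05. The other splits divided the 3 libraries of a line unevenly, so part of the real difference between the lines stayed in them. Their list counts are therefore not a rate expected by chance. For APC-responsive genes 1 of 100 splits drawn from 840 reached 7951, the real one. Every drawn split that mixed APC libraries with those of the other lines gave 0 genes, since mixing lines this different widens the spread within groups. The libraries of a group were plates of 1 line, so the splits cannot exclude chance differences between lines. The highest other split gave 6800, and both other splits with over 0 genes kept the 3 APC libraries together.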

How the results depend on the processing

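Leaving out the ribosomal RNA precursor was chosen after the data were seen. A minimum fold of 2 tests a different question and left 2050 genes in APC against SW480, 1940 in APC against CONTROL, 223 in CONTROL against SW480 and 1544 APC-responsive genes. With an estimated correlation 2, 2 and 1 lists passed, and with fry, which does not compare a list with other genes, 27, 26 and 22. In the other 10 settings the gene counts were 9008 to 10928, 8745 to 10530 and 5944 to 7372, with 6956 to 8293 responsive genes. Leaving out 1 library gave 9913 to 10386, 9447 to 10260 and 6185 to 7299 genes, 7596 to 8055 responsive genes, and 8 to 11, 9 to 10 and 6 to 10 lists. Without the ribosomal RNA precursor the counts were 10327, 10004, 7149 and 7965. Other scalings moved the median of all genes by at most 0.012 on the log2 scale. Named genes were followed over at most 16 alternatives per pair of a gene and a comparison. These left out the minimum fold of 2, the fits of 6 libraries, the RPKM fit without a filter and the fit without the ribosomal RNA precursor. Of 408 pairs, 9 had a call that changed under some of these alternatives, in 8 genes (CDH1, CDX2, DLL4, FAS, ERAP1, TM7SF2, PRRX1 and CD68), and 0 reversed.

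With the replicate number as a replicate block, 10295, 9991 and 7109 genes were called, 7946 were APC-responsive, and 9 lists passed in each comparison. Same-numbered libraries correlated in their deviations at −0.069 to 0.106, with 1 of 9 pairs over 0.1, and 2 of 18 correlated best with their own number, so the numbers do not pair the samples.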

Other observations

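The gene families below were chosen after their values were seen, and their members can share exons or reads, so values per gene are uncertain. All 15 tested protocadherin alpha genes and all 22 protocadherin gamma genes, which encode neuronal adhesion molecules from clusters with shared exons, were higher in the APC line than in both other lines, with median log2 fold changes against SW480 of 3.47 and 0.78, and all of them were lower in CONTROL than in SW480. There the alpha genes spanned only −1.74 to −1.62 and the gamma genes −0.67 to −0.61. The genes of a cluster may thus largely repeat the same reads, so they do not count as separate observations. Of 9 tested HOXB genes, which encode patterning transcription factors, 8 were lower in the APC line than in both other lines, with medians of −1.45 against SW480 and −1.02 against CONTROL, and HOXB13 was the exception. All 9 were also lower in CONTROL than in SW480, with a median of −0.55. Around the HOXB genes, a stretch of 26 genes from OSBPL7 to IGF2BP1 had a median of −0.58 in APC against SW480. The same genes had medians of −0.41 in APC against CONTROL and −0.23 in CONTROL against SW480. HOXB genes may count among the 26, so whether their changes are shared with the genes around them was not tested separately. All 6 tested PSG genes, which encode pregnancy-specific glycoproteins, were lower, with medians of −4.88 against SW480 and −4.68 against CONTROL, and 2 of them were also lower in CONTROL than in SW480.

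The longest stretches of shifted neighbours in APC against CONTROL ran from ALG10B to HMGA2, with 198 genes at a median log2 fold change of −0.67 (−0.48 in APC against SW480), and from HPS1 to EBF3, with 129 genes at 0.51 (0.57 in APC against SW480). In APC against SW480 a stretch of 178 genes from SLC6A20 to DZIP3 had a median of −0.54, and the same genes had medians of −0.43 in CONTROL against SW480 and −0.13 in APC against CONTROL. Stretches shifted in the same direction in both APC comparisons held 847 genes. Of these, 697 were APC-responsive, and 651 moved with the stretch. The responsive share was 82.3% there, against 55.8% elsewhere, but the stretches were found from the same fold changes, so part of this difference is built in.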
